A study of Rattus norvegicus with 6 samples.

How the data were processed

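Rat airway basal cells were grown from scrapings of the tracheal lining of male wild-type Sprague Dawley rats aged 12 weeks and weighing 370 ± 39 g, per the labels' protocols. Basal cells are the stem cells of the airway lining. The labels describe 3 cell lines, each pooled from 3 rats. On isolation, each line was divided between BEGM, a bronchial epithelial growth medium, and EpiX, another epithelial culture medium, and RNA was taken after 8 days of culture and a DNase digestion. Each culture gave 1 array, so there were 6 arrays, 3 per medium. The sample number in the labels (1, 2 or 3) was used as the replicate number.

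The labels state that biotin-labelled RNA was processed by the Affymetrix protocol, and the submitters' processing notes name the Transcriptome Analysis Console, without its role or version. The authors' deposited log2 values hold 1 signal per probe set and array for 24834 probe sets, and the steps by which the authors made them are not given in the sources used here. The unit was taken as log2 from the values, which ran from 2.62 to 18.66 over all arrays. The scale, the base of the logarithm, the normalization and the centring therefore stay unknown. Every fold below assumes base 2. The median over the tested genes was 6.98, 7.02 and 7.13 on the BEGM arrays 1, 2 and 3, and 6.93, 6.93 and 6.90 on the EpiX arrays 1, 2 and 3. Scanner files and detection calls were not used here, so no probe set could be called present or absent. The number of arrays limits the precision of every value.

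Genes were named through the platform annotation, which can be old, and whose symbols were compared with a RefSeq gene table. Of the probe sets, 15049 had 1 gene symbol and 0 had several. Another 8139 had none and were left out of the gene test, together with 63 ERCC, 399 exon, 1153 intron and 31 hybridisation, spike and background controls. For 10 genes with several probe sets the brightest was kept, which set aside 12 probe sets and left 15037 genes. The probe sets of 2 of these genes differed in direction between the media. Krt5 and Muc5ac had no named probe set and were not analysed here.

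All tests were made with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and plots with matplotlib 3.10.9. A linear model with the medium as its only term was fitted to the 6 arrays (lmFit and eBayes), with no filter on dim probe sets and no further normalization. Differences are EpiX minus BEGM on the log2 scale, and p-values are 2-sided. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 over the 15037 genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and called at a BH-adjusted p under 0.05 over 27 lists. These lists held 456 members, of which 386 were measured and 70 had no named probe set. They covered airway cell types (basal, secretory, luminal, ciliated, squamous and hillock, and rare epithelial cells), other cell types a scraping can hold (fibroblast, smooth muscle and cartilage, leukocyte, endothelial), growth (mitosis, DNA replication, p53 and senescence), signalling (TGF-beta and mesenchymal transition, BMP, Notch, Wnt, YAP and TAZ, EGF receptor and MAP kinase, retinoic acid, glucocorticoid), and stress, immune and metabolic responses (interferon, inflammatory, cholesterol, glycolysis and hypoxia, unfolded protein and amino acid stress, NRF2 and aryl hydrocarbon). A gene or list is said to have risen, fallen or changed only where it passed its test.

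The main tests, the lists, the other settings below and the rule for named genes were fixed before the data were examined, and tests and settings added later are said to be so where they are given. Named genes were the 10 largest differences in each direction among called genes that changed the same way in all 3 same-numbered pairs, with predicted and unnamed loci passed over. Up to 4 called members of each list were added, those with the largest differences, or 2 members as values only where none was called. Krt14, Tp63, Ngfr, Scgb1a1, Foxj1, Krt8, Krt13, Mki67, Vim, Col1a1, Ptprc and Cdkn1a were always named. Further list members are named where a group is described, and these were chosen after their values were seen.

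Each line was divided between the media, but the labels do not say which line a sample number stands for. Same-numbered arrays were taken as cultures of the same line. The titles set the same arrays side by side, but give the number 3 to the arrays numbered 2 here and no number to those numbered 3. Over genes, the deviations of same-numbered arrays from their group means correlated at 0.32 for number 1, -0.01 for number 2 and 0.32 for number 3, while arrays of other numbers correlated at -0.37 to 0.16. A fit with the number as a block was run as an alternative. The other alternatives were a random block for the number, quantile normalization, centring of each array on its median, leaving out the dimmest 25% of genes, a trended and robust variance, array weights, the mean of a gene's probe sets, other thresholds, an estimated inter-gene correlation, the rotation test fry, a rank-based camera, and leaving out each number and each array in turn. The pipeline was tested on simulated data with the gene spreads of these arrays shuffled over genes, with 200 of the 15037 genes changed in each of 5 runs. The simulated noise was independent between genes and alike on all arrays, with no array that deviated as BEGM array 1 did. The spreads were those moderated by eBayes and were given to genes without regard to the size of their change. On the real arrays some large differences had wide spreads. Col1a1 and Col1a2 were 14.5-fold and 13.1-fold lower in EpiX without passing, with SEs of 1.16 and 0.94 against a median SE of 0.19. The rates below hold for the simulated noise and may be too favourable for the real arrays, above all for such genes. The pipeline recovered 3.2% of genes changed 1.5-fold, 44.4% of those changed 2-fold, 94.0% of those changed 4-fold and 99.6% of those changed 8-fold, with 32 false calls over the 5 runs.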

Results

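Expression of 15037 genes was measured in rat tracheal basal cells after 8 days in BEGM (3 arrays) or EpiX (3 arrays). The comparison asked how the culture medium changes cells of the same 3 lines. On the first principal component, which held 69.7% of the variance, the EpiX arrays 1, 2 and 3 scored 53.9, 47.1 and 34.2. The BEGM arrays 2 and 3 scored -54.8 and -73.2, while BEGM array 1 scored -7.24 and lay between the media. Across genes, which are not independent replicates, the EpiX arrays correlated with each other at 0.989 to 0.996. BEGM array 1 correlated at 0.986 with BEGM array 2, at 0.977 with BEGM array 3 and at 0.982 to 0.985 with the EpiX arrays. The median of the intron control probe sets was 5.11, 5.16 and 5.29 on the BEGM arrays and 5.24, 5.30 and 5.56 on the EpiX arrays, highest on EpiX array 3.

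**Figure D1:**
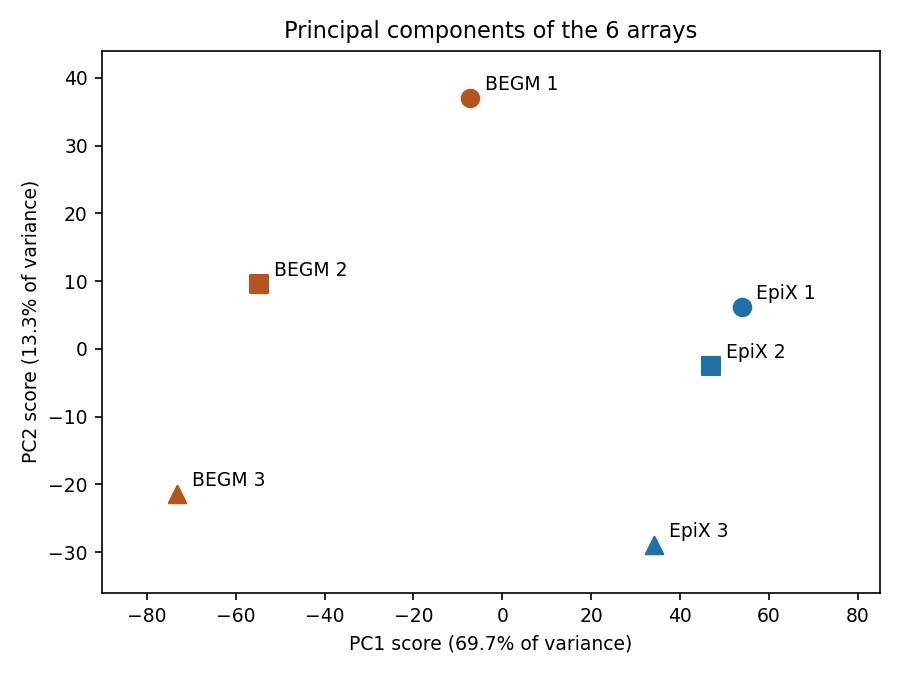
Scores of the 6 arrays on the first (horizontal, 69.7% of variance) and second (vertical, 13.3% of variance) principal components of the deposited log2 values of the tested genes; colours mark the medium and symbols the sample number. The EpiX arrays lie at 34.2 to 53.9 on the first component and BEGM array 1 lies at -7.24, between them and the other BEGM arrays.

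Cells in EpiX had lower levels of 12 of 19 measured genes of TGF-beta response and mesenchymal transition than the same lines in BEGM, and higher levels of 6 of 15 basal cell genes, of which another 2 were lower, and of 9 of 18 mitosis genes. The chemokine Ccl2 fell by 10.01 ± 0.67 (SE, n = 3 per medium; adjusted p = 0.00168), from 16.07 ± 1.36 (SD) in BEGM to 6.06 ± 0.65 in EpiX. The matrix proteoglycan Bgn fell by 9.80 ± 1.08 (SE) and the muscle actin Acta1 by 8.50 ± 0.64. The largest rises were those of the water channel Aqp5, by 5.86 ± 0.83 (adjusted p = 0.0131), and the kallikrein peptidase Klk10, by 5.51 ± 1.09 (adjusted p = 0.0359). Tp63, the transcription factor that maintains basal cells, rose by 2.15 ± 0.20 (adjusted p = 0.00431).

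In all, 869 genes (5.78% of those tested) differed between the media by limma at a BH-adjusted p under 0.05. Of these, 395 were higher and 474 lower in EpiX, and all 869 changed the same way in the 3 same-numbered pairs. With each array centred on its median the counts were 560 higher and 409 lower, and the median of all differences moved to 0.13. At least 2-fold changes made up 675 of the calls, 278 higher and 397 lower. Changes of 16-fold or more were found for 54 genes lower in EpiX and 8 higher. Of the genes called lower, 25 lay in EpiX under 4.48, the limit of the dimmest 25%, and 6 of those called higher did so in BEGM. The count of calls changed when single arrays were left out, which also leaves fewer samples for the test. It was 2089 without BEGM array 1, 192 without BEGM array 2, 544 without BEGM array 3, 170 without EpiX array 1, 101 without EpiX array 2 and 418 without EpiX array 3. Without both arrays of number 1 it was 1351, without those of number 3 it was 264, and without those of number 2 it was 0 by limma, with 1582 genes at an unadjusted p under 0.05. Of the 72 named genes that were called, 5 lost the call without number 1, 31 without number 3 and all 72 without number 2. Leaving out single arrays ended 39 of these 72 calls without BEGM array 2, 19 without BEGM array 3, 41 without EpiX array 1, 48 without EpiX array 2 and 22 without EpiX array 3.

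The other largest rises were those of the potassium channel Kcnj15 (4.98 ± 0.25, SE), the carbonic anhydrase Car12 (4.74 ± 0.34), the kallikrein Klk13 (4.60 ± 0.52), the basal keratin Krt15 (4.12 ± 0.71), the water and glycerol channel Aqp3 (4.09 ± 0.22), the chemokine Cxcl17 (4.04 ± 0.24), the prostaglandin-degrading enzyme Hpgd (3.85 ± 0.83) and the growth factor binding protein Igfbp2 (3.57 ± 0.25). The other largest falls were those of the secreted phosphoprotein Spp1 (-7.81 ± 1.13), the collagen cross-linking enzyme Loxl2 (-7.76 ± 0.69), the TGF-beta target Pmepa1 (-7.67 ± 0.59), Prnd (-7.17 ± 0.65), the adhesion molecule Ncam1 (-7.13 ± 0.70), the pyrophosphate-producing enzyme Enpp1 (-7.12 ± 0.70) and the growth factor Bmp4 (-7.03 ± 1.14). BEGM array 1 was the lowest of the BEGM arrays for each of the 10 largest falls, with Bgn at 13.70 against 16.26 and 17.38 and Ccl2 at 14.50 against 16.79 and 16.91.

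**Figure D2:**
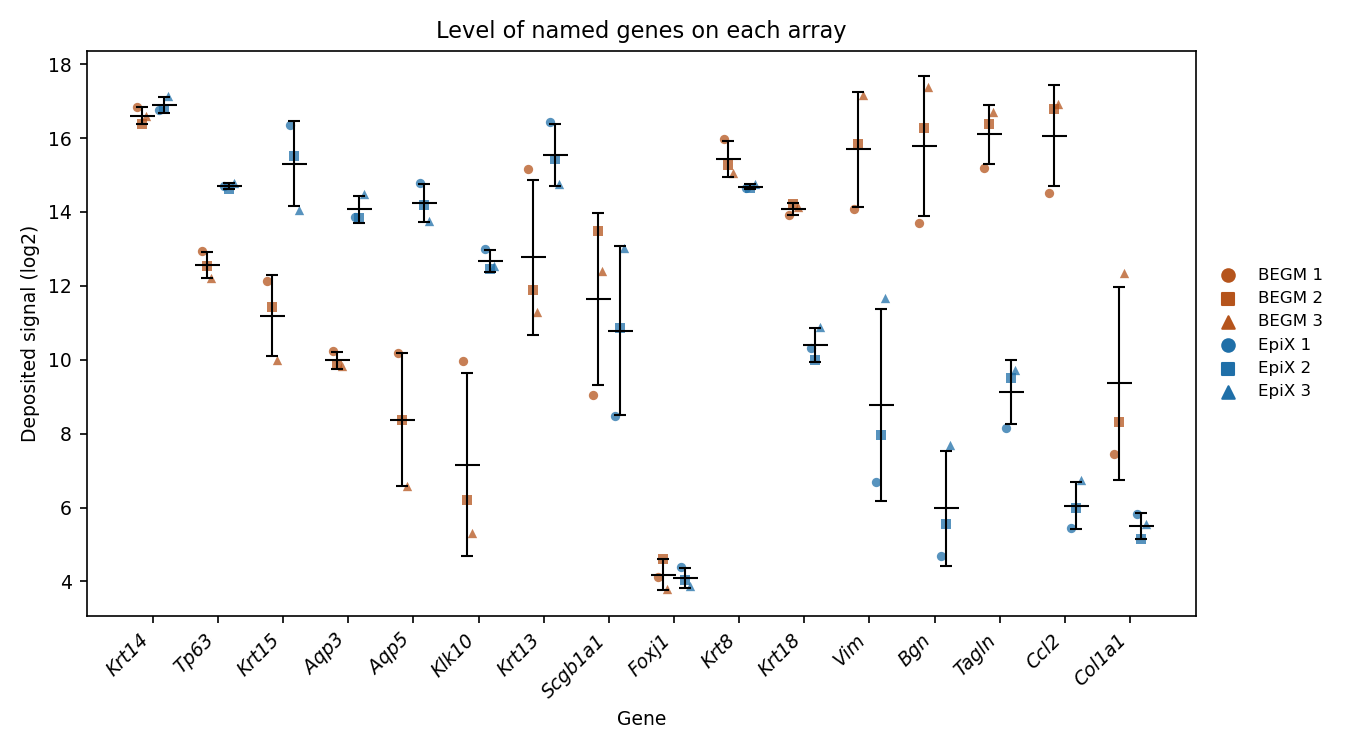
Deposited log2 signal (vertical) of 16 named genes (horizontal) on each array; coloured symbols are single arrays, and black bars are the mean and SD of the 3 arrays of a medium. Ccl2 averaged 16.07 in BEGM and 6.06 in EpiX, Aqp5 averaged 8.38 and 14.24, and Krt14 averaged 16.61 and 16.89.

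Camera called 14 of the 27 gene lists, 8 higher and 6 lower in EpiX. With the correlation estimated from the data, camera called 0 lists, the smallest adjusted p being 0.257, so every list call by camera below depends on the preset correlation. The self-contained test fry called 8 lists, 7 of them among these 14 and the other the BMP response list. It did not call the lists of squamous differentiation and hillock (adjusted p = 0.125), fibroblasts (0.159), DNA replication (0.147), inflammatory response (0.053), cholesterol synthesis (0.269), EGF receptor and MAP kinase response (0.0528), and unfolded protein and amino acid stress (0.125).

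The list of TGF-beta response and mesenchymal transition fell: 12 of 19 measured members fell, 0 rose and 7 did not pass, and 18 fell when adjusted over the list alone (camera adjusted p = 6.12e-16; adjusted p = 0.26 with an estimated correlation). Its median difference was -2.98. Besides Pmepa1, the largest falls were those of the actin-binding protein Tagln (-6.97 ± 0.53, SE), the intermediate filament Vim (-6.92 ± 1.33) and the matrix protein Thbs1 (-6.77 ± 1.10). Vim was at 14.08, 15.83 and 17.18 on the BEGM arrays 1, 2 and 3 and at 6.68, 7.96 and 11.68 on the EpiX arrays. Mean levels over the list were 10.26, 11.39 and 12.20 on the BEGM arrays and 7.20, 7.57 and 8.17 on the EpiX arrays. The number of members that fell was 17 without BEGM array 1 and 9 without both arrays of number 3.

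The list of YAP and TAZ response, targets of the Hippo pathway's co-activators, also fell (camera adjusted p = 2.04e-06; adjusted p = 0.257 with an estimated correlation). Of its 10 measured members 6 fell, 0 rose and 4 did not pass, with 7 falling when adjusted over the list alone. Examples were Tgfb2 (-3.04 ± 0.23, SE), tissue factor F3 (-2.64 ± 0.26), the receptor kinase Axl (-2.32 ± 0.49) and the kinase Lats2 (-1.89 ± 0.30). Without the arrays of number 3, 3 members fell.

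The fibroblast list fell as a list, with a median of -1.53 over 16 members (camera adjusted p = 6.28e-05; adjusted p = 0.405 with an estimated correlation). By limma 0 of its members were called, also when adjusted over the list alone, but 8 fell without BEGM array 1, 4 with the number as a block and 1 without the arrays of number 3. The collagen genes Col1a1 (-3.86 ± 1.16, SE; adjusted p = 0.109) and Col1a2 (-3.71 ± 0.94; adjusted p = 0.072) did not pass, and Col1a2 had an adjusted p of 0.0405 with the number as a block. Col1a1 was at 7.44, 8.32 and 12.34 on the BEGM arrays 1, 2 and 3, so the difference lay mostly in BEGM array 3. Mean levels over the fibroblast list were 6.13, 6.96 and 8.85 on the BEGM arrays and 5.39, 5.33 and 5.87 on the EpiX arrays. The smooth muscle and cartilage list fell, with a median of -0.29 over 11 members (camera adjusted p = 0.0141; adjusted p = 0.26 with an estimated correlation). This rested on few genes: 1 member fell, the smooth muscle protein Cnn1 (-7.00 ± 0.74), with 2 adjusted over the list alone and 2 without BEGM array 1.

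The basal cell list rose (camera adjusted p = 0.000226; adjusted p = 0.26 with an estimated correlation). Of 15 measured members 6 rose, 2 fell and 7 did not pass, and adjusted over the list alone 7 rose and 2 fell. Krt15 and Aqp3 led, followed by the cell adhesion molecule Bcam (3.11 ± 0.19, SE). The membrane glycoprotein Pdpn fell by 2.96 ± 0.21, and the laminin chain Lamb3 also fell (-1.20 ± 0.17). The basal keratin Krt14 was at 16.61 ± 0.24 (SD) in BEGM and 16.89 ± 0.21 in EpiX, a difference of 0.29 that did not pass (adjusted p = 0.423). The nerve growth factor receptor Ngfr, a surface marker of basal cells, differed by 0.34 ± 0.15 (SE; adjusted p = 0.253). Without the arrays of number 3, 4 members rose and 1 fell.

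The list of squamous differentiation and hillock genes, which mark stratified and hillock epithelium, rose with a median of 1.27 (camera adjusted p = 4.77e-05; adjusted p = 0.403 with an estimated correlation). Of 17 measured members 1 rose, the galectin Lgals7 (2.76 ± 0.48, SE), 0 fell and 16 did not pass, with 3 rising when adjusted over the list alone. The hillock keratin Krt13 differed by 2.76 ± 0.99 (adjusted p = 0.16, and 0.0284 with the number as a block). BEGM array 1 was close to the EpiX arrays over this list: its mean level was 12.33, against 10.64 and 10.46 on the other BEGM arrays and 12.74, 12.58 and 12.38 on the EpiX arrays. Without BEGM array 1, 11 members rose, with the number as a block 6 rose, and without the arrays of number 3, 0 rose by limma.

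The luminal epithelium list was not called (median -0.47 over 14 members, camera adjusted p = 0.103). It held 1 fall, that of the simple-epithelial keratin Krt18 (-3.68 ± 0.24, SE), which was 1 also when adjusted over the list alone, and its partner Krt8 did not pass (-0.74 ± 0.25, adjusted p = 0.137). Its rises numbered 3 without BEGM array 1, and with the number as a block 3 members rose and 2 fell. The list was called lower without the arrays of number 3 (adjusted p = 0.0306), without BEGM array 3 (0.00288), without EpiX array 1 (0.0263), with median centring (0.0376) and with the random block (0.0235). Its mean difference was -0.12 in the main fit but positive in other settings. It was 0.34 without BEGM array 1, 0.11 without the arrays of number 1, 0.07 with array weights and 0.0085 with median centring. The secretory cell list was not called (median 0.13 and mean 0.72 over 17 members, camera adjusted p = 0.139), with 3 rises, 0 falls and 14 that did not pass, and 4 rises when adjusted over the list alone. These 3 were the immunoglobulin receptor Pigr (2.34 ± 0.28), the cytochrome Cyp2f4 (1.74 ± 0.30) and Lypd2 (1.20 ± 0.24), whose adjusted p was 0.0531 with the number as a block, a fit in which 1 other member fell. Without the arrays of number 3, 0 members rose by limma, and without those of number 2 the list was called (adjusted p = 0.0492). The club-cell protein Scgb1a1 was at 9.03, 13.49 and 12.40 on the BEGM arrays 1, 2 and 3 and at 8.49, 10.85 and 13.04 on the EpiX arrays, a difference within the spread between arrays (-0.85 ± 1.43, SE; adjusted p = 0.786).

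The ciliated cell list was not called (camera adjusted p = 0.896), with 0 of 11 measured members called, also over the list alone, and its median (-0.05) and mean (0.05) differed in sign. Its largest differences were those of Tppp3 (1.16 ± 0.31, SE; adjusted p = 0.0833) and the tektin Tekt2 (-0.53 ± 0.19; adjusted p = 0.159). Foxj1, the master regulator of motile cilia, was dim in both media at 4.18 ± 0.42 (SD) and 4.10 ± 0.27. The list of rare epithelial cells was not called (median -0.02 over 16 members, camera adjusted p = 0.329), with 1 fall in both adjustments (2 with the number as a block), that of the tuft-cell kinase Dclk1 (4.87 ± 0.07, SD, in BEGM and 3.86 ± 0.20 in EpiX), which was dim in EpiX. The leukocyte list was not called (median -0.13 over 15 members, camera adjusted p = 0.463). Its 1 fall in both adjustments was that of the invariant chain Cd74 (-1.31 ± 0.27, SE), which was also dim in EpiX and had an adjusted p of 0.0526 with the number as a block, which left 0 falls. Neither Dclk1 nor Cd74 was called without the arrays of number 3. The pan-leukocyte gene Ptprc was dim in both media (4.09 ± 0.07 and 3.89 ± 0.17, SD). The endothelial list was not called (median -0.38 over 9 members, camera adjusted p = 0.106), with 0 members called and 1 falling when adjusted over the list alone. Its largest differences were those of Esam (-1.51 ± 0.38, SE; adjusted p = 0.0685) and Tek (-0.90 ± 0.37, adjusted p = 0.209). Esam was the 1 member that fell by limma without BEGM array 1 (adjusted p = 0.00775), and it also fell with array weights (0.0151).

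**Figure D3:**
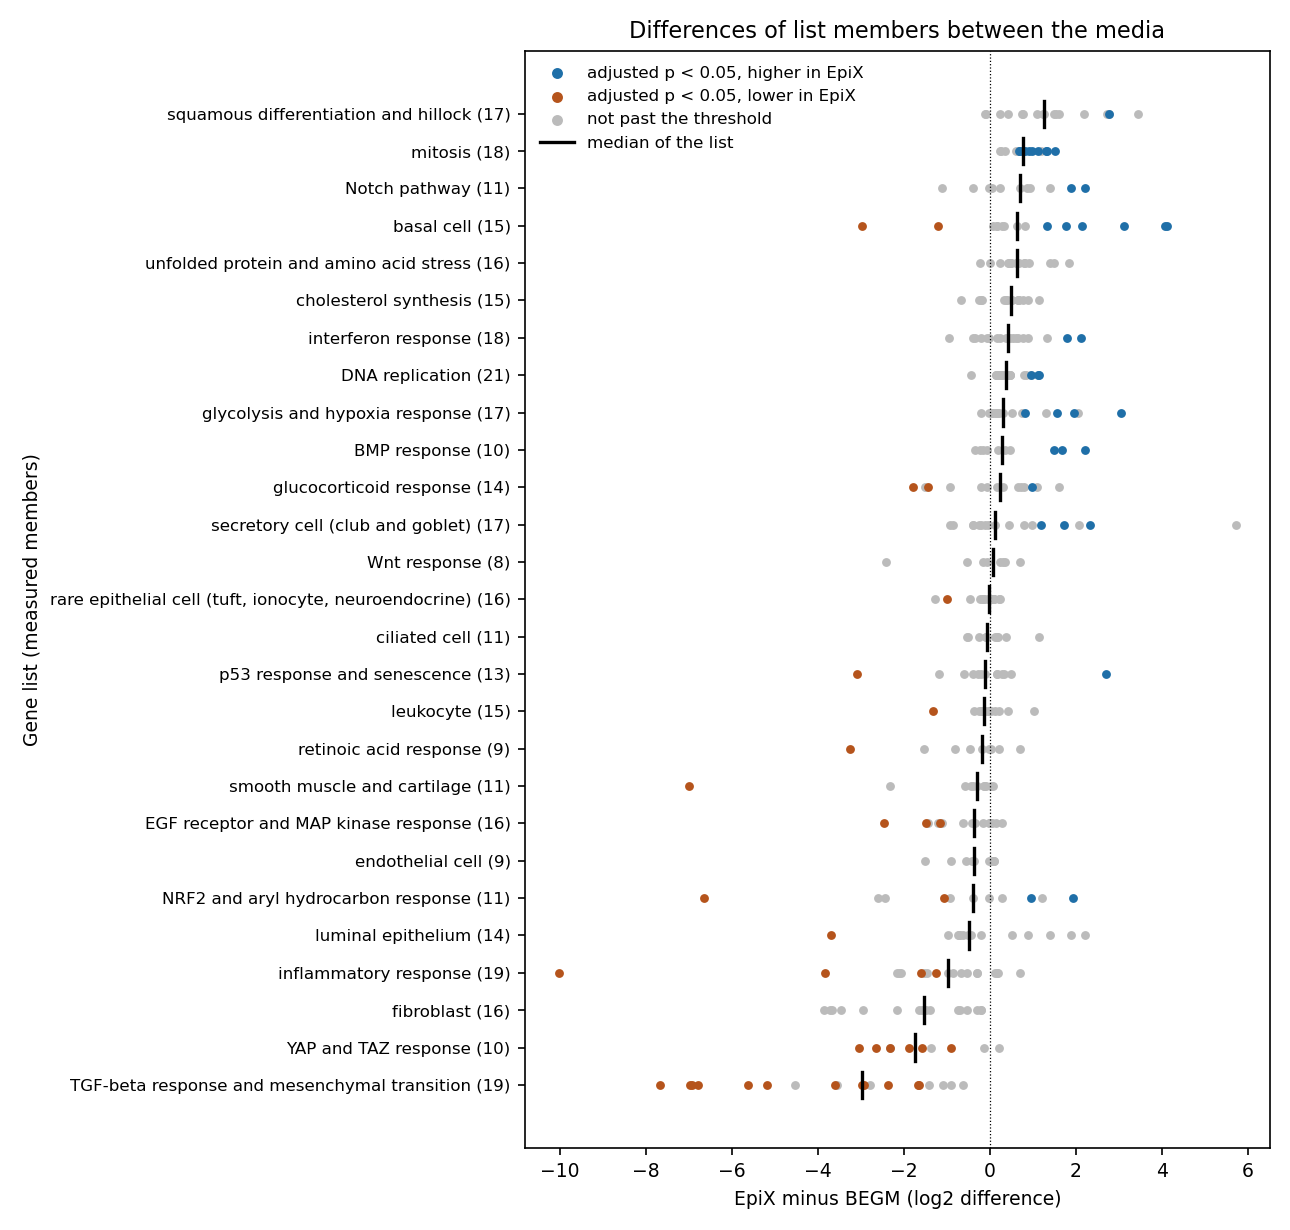
Difference between the media (horizontal, log2, EpiX minus BEGM) of the measured members of each gene list (vertical); each point is 1 gene, coloured where its adjusted p was under 0.05, and black bars are list medians. The list medians run from -2.98 (TGF-beta response and mesenchymal transition) to 1.27 (squamous differentiation and hillock).

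The mitosis list rose with a median of 0.77 (camera adjusted p = 5.49e-11; adjusted p = 0.26 with an estimated correlation). Of 18 measured members 9 rose, 0 fell and 9 did not pass, with 14 rising when adjusted over the list alone. Examples were Cenpf (1.53 ± 0.21, SE), Nusap1 (1.34 ± 0.18), the cyclin Ccnb2 (1.30 ± 0.14) and the spindle motor Kif11 (1.13 ± 0.21). The proliferation marker Mki67 differed by 1.19 ± 0.30 (adjusted p = 0.0675, and 0.0254 with the number as a block). The DNA replication list rose with a median of 0.38 (camera adjusted p = 0.000119; adjusted p = 0.446 with an estimated correlation). Of 21 measured members 3 rose, 0 fell and 18 did not pass, with 4 rising when adjusted over the list alone. The 3 were the polymerase subunit Pola1 (1.14 ± 0.18), the ribonucleotide reductase subunit Rrm2 (1.12 ± 0.23, adjusted p = 0.0529 with the number as a block) and Cdc45 (0.95 ± 0.13). Without the arrays of number 3, 3 mitosis members and 0 replication members rose by limma.

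The list of p53 response and senescence was not called (median -0.11 over 13 members, camera adjusted p = 0.568). The senescence-associated cell cycle inhibitor Cdkn2a fell by 3.07 ± 0.50 (SE) and the stress cytokine Gdf15 rose by 2.70 ± 0.39. Adjusted over the list alone, 1 member rose and 3 fell. There were 2 falls without BEGM array 1, and 0 rises by limma without the arrays of number 3. Cdkn1a, the main cell cycle inhibitor induced by p53, differed by -0.11 ± 0.13 (adjusted p = 0.694) and by 0.0159 with each array centred on its median.

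Among signalling lists, the Notch pathway rose with a median of 0.71 (camera adjusted p = 0.0116; adjusted p = 0.361 with an estimated correlation). Of 11 measured members 2 rose, the receptor Notch1 (2.22 ± 0.29, SE) and its ligand Dll1 (1.89 ± 0.19), and 0 fell, with 4 rising when adjusted over the list alone. Without BEGM array 1, 4 members rose and 1 fell. The list's call ended without EpiX array 3 (adjusted p = 0.0505) and without both arrays of number 3 (adjusted p = 0.061). The list of EGF receptor and MAP kinase response fell with a median of -0.37 (camera adjusted p = 0.00805; adjusted p = 0.298 with an estimated correlation). Of 16 measured members 3 fell and 0 rose: the phosphatase Dusp6 (-2.46 ± 0.48), Phlda1 (-1.48 ± 0.23) and the ligand Hbegf (-1.15 ± 0.24). Adjusted over the list alone 5 fell, without BEGM array 1 6 fell, and without the arrays of number 3 0 fell by limma.

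The BMP response list was not called (median 0.28 over 10 members, camera adjusted p = 0.0964), although the inhibitors of differentiation Id1 (2.22 ± 0.30, SE), Id3 (1.67 ± 0.35) and Id4 (1.48 ± 0.31) rose, 3 in both adjustments. It was called without the arrays of number 2 (adjusted p = 0.0364), without EpiX array 2 (0.0423), with the random block (0.0456) and by fry (0.024), and 1 member rose without the arrays of number 3. The Wnt response list was not called (camera adjusted p = 0.768), with 0 of 8 measured members called, also over the list alone, and its median (0.08) and mean (-0.19) differed in sign. Its largest differences were those of Lef1 (-2.41 ± 0.79, adjusted p = 0.134), which fell without BEGM array 1 (adjusted p = 0.0004), and Nkd1 (0.71 ± 0.24, adjusted p = 0.141). The retinoic acid response list was not called (median -0.19 over 9 members, camera adjusted p = 0.201), with 1 fall in both adjustments, that of the transglutaminase Tgm2 (-3.24 ± 0.54). Leaving out BEGM array 1 gave 1 rise and 2 falls in it, and the number as a block 2 falls. The glucocorticoid response list was not called (median 0.24 over 14 members, camera adjusted p = 0.66). Per1 rose (0.99 ± 0.21), while the kinases Sgk1 (-1.78 ± 0.31) and Pdk4 (-1.44 ± 0.30), which was dim in EpiX, fell, and adjusted over the list alone 4 members rose and 3 fell. Its rises numbered 2 without BEGM array 1 and with the number as a block, and it had 0 rises and 1 fall by limma without the arrays of number 3.

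The inflammatory response list fell with a median of -0.97 (camera adjusted p = 0.000119; adjusted p = 0.361 with an estimated correlation). Of 19 measured members 4 fell, 0 rose and 15 did not pass, and adjusted over the list alone 8 fell and 1 rose. The 4 were Ccl2, the cytokine Il1a (-3.83 ± 0.74, SE), the neutrophil chemokine Cxcl1 (-1.60 ± 0.30) and the growth factor Csf2 (-1.24 ± 0.17). The interferon response list was not called (median 0.42 over 18 members, camera adjusted p = 0.0785), with 2 rises, those of the antiviral genes Rsad2 (2.11 ± 0.23) and Oasl (1.79 ± 0.30), and 2 rises and 1 fall when adjusted over the list alone. It was called with the number as a block (adjusted p = 0.0237), with the random block (0.0456), with array weights (0.0429), without the arrays of number 1 (0.0118), without BEGM array 1 (0.022) and without BEGM array 2 (0.0407). It had 4 rises without BEGM array 1, 1 fall with the number as a block and, by limma, 0 rises without the arrays of number 3.

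The list of glycolysis and hypoxia response rose with a median of 0.32 (camera adjusted p = 0.000248; adjusted p = 0.361 with an estimated correlation). Of 17 measured members 4 rose, 0 fell and 13 did not pass, with 5 rising when adjusted over the list alone. The 4 were the vasodilator peptide Adm (3.06 ± 0.51, SE), the kinase Pdk1 (1.95 ± 0.29), the hexokinase Hk2 (1.57 ± 0.14) and Vegfa (0.82 ± 0.16), and 2 members rose without the arrays of number 3. The cholesterol synthesis list rose with a median of 0.50 (camera adjusted p = 0.0125; adjusted p = 0.601 with an estimated correlation), with 0 of 15 measured members called, also over the list alone, and 7 rising without BEGM array 1. Insig1 (1.14 ± 0.32, adjusted p = 0.092) and Stard4 (0.90 ± 0.21, adjusted p = 0.0554) differed most. The call of this list ended without the arrays of number 2 (adjusted p = 0.0933) or number 3 (0.387), and without BEGM array 2 (0.0715), BEGM array 3 (0.0509) or EpiX array 3 (0.183).

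The list of unfolded protein and amino acid stress rose with a median of 0.62 (camera adjusted p = 0.000106; adjusted p = 0.403 with an estimated correlation). By limma 0 of its 16 members were called, and 4 rose when adjusted over the list alone. The pseudokinase Trib3 differed by 1.84 ± 0.75 (SE; adjusted p = 0.207, and 0.028 with the number as a block) and the glutathione-degrading enzyme Chac1 by 1.49 ± 0.38 (adjusted p = 0.0722, and 0.0115 with the block). Without BEGM array 1, 2 members rose, with the number as a block 5 rose, and without the arrays of number 3, 1 rose. The NRF2 and aryl hydrocarbon list was not called (median -0.40 over 11 members, camera adjusted p = 0.605), and its members moved both ways. The cytochrome Cyp1b1 (-6.64 ± 1.38) and the reductase Txnrd1 (-1.05 ± 0.20) fell, while the cystine transporter Slc7a11 (1.94 ± 0.38) and Srxn1 (0.97 ± 0.19) rose. Adjusted over the list alone 3 rose and 4 fell, 4 fell without BEGM array 1 and also with the number as a block, and without the arrays of number 3 0 rose and 0 fell by limma.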

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

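The tests below of fibroblasts, of the normalization, and of the position of BEGM array 1 were chosen after the results were seen, as was their bar of interquartile ranges that lie apart, whereas the counts over other splits of the arrays were planned.

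A signal appeared in probe sets that the gene comparison left out. Of 8139 unnamed probe sets, 221 passed a BH-adjusted p under 0.05 by limma, 106 higher and 115 lower in EpiX, against 0 of the 63 ERCC, 399 exon, 1153 intron and 31 other control probe sets. At an unadjusted p under 0.05 there were 1539 unnamed probe sets, 49 exon controls, 82 intron controls and 0 of the other kinds. The largest fall was that of a probe set at 16.18 in BEGM and 7.30 in EpiX, a difference of -8.88, which is in the range of the largest named falls. Which genes these probe sets measure was not analysed here.

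There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The split by medium called 869 genes and the highest other split 0, so 1 of the 10 splits gave as many genes. For gene lists the split by medium called 14, the highest other split 8 and the lowest 2, so 1 of the 10 gave as many lists. Every split that mixed the media thus called some lists at the preset correlation. The 3 splits that set BEGM arrays 2 and 3 with 1 EpiX array against BEGM array 1 with the other EpiX arrays each called 8 lists at the preset correlation.

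The first pattern is the set of 54 genes at least 16-fold lower in EpiX, among them Vim, Bgn, Tagln, Mmp2 and Cnn1. After quantile normalization 53 of the 54 stayed at least 16-fold lower, so differences left between the array distributions do not account for them. Upper quartiles ran from 10.48 (EpiX array 3) to 10.52 (EpiX array 1), medians from 6.90 (EpiX array 3) to 7.13 (BEGM array 3) and lower quartiles from 4.46 (EpiX array 1) to 4.59 (BEGM array 2). These ranges are small beside a log2 difference of 4, so the step could change little for the 54 genes. It cannot decide on the authors' own normalization, which is unknown. Fibroblasts as the whole source would step alike with the 54 genes between BEGM arrays, and the 54 and the 16 listed fibroblast members had interquartile ranges apart in 1 of 3 steps, from array 1 to 2 (medians 1.97 and 0.70), but not from 2 to 3 (0.44 and 2.31) or from 1 to 3 (2.77 and 2.78), so fibroblasts cannot be told apart from other sources. This test was settled on after its values were seen, and a comparison with the EpiX arrays was dropped because the 54 genes were chosen for that difference. The abundant fibroblast genes Col1a1, Col1a2 and Col3a1 stood at 7.44, 8.19 and 7.82 on BEGM array 1 and at 12.34, 12.35 and 10.54 on BEGM array 3. On BEGM array 2, Col1a1 and Col1a2 stood at 8.32 and 9.45, nearer to array 1, although the 54 genes had stepped up by a median of 1.97. A share of fibroblasts may thus contribute, more in the culture of BEGM array 3. A change of the epithelial cells themselves with the medium, which the design names, also stays open and was not tested, as does a mesenchymal cell type low in the listed markers.

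The second pattern is the position of BEGM array 1 between the media. A swap with an EpiX sample is argued against, because the lowest correlation between EpiX arrays was 0.989 and the highest of an EpiX array with BEGM arrays 2 or 3 was 0.971. EpiX material mixed into this sample is argued against as the whole cause. Genes were chosen where BEGM arrays 2 and 3 both lay at least 2 (log2) above, or below, all EpiX arrays. The 206 such genes higher in BEGM needed a share of 0.687 at their lower quartile, or 0.584 and 0.536 if the deposited scale stretches differences 1.5-fold or 2-fold. Of the 79 such genes higher in EpiX, 52, 34 and 21 lay below that share of the lowest EpiX signal, with Car12 at 7.63 on BEGM array 1 and 11.63 to 13.01 on the EpiX arrays. On an EpiX array at most 17, 2 and 0 did so. The EpiX arrays had served to choose these genes and BEGM array 1 had not, which favours low counts on the EpiX arrays. A lower share of mesenchymal cells alone would lift epithelial genes alike. BEGM array 1 exceeded the other BEGM arrays by a median of 0.36 (interquartile range -0.16 to 0.40) over the basal list and 1.03 (0.53 to 2.35) over the luminal list. These ranges lay apart, but by a first bar, medians further apart than the larger range is wide, this cause would have stayed open. The basal list also holds Ngfr, which was near the dim limit (4.69 on BEGM array 1), and Pdpn, which was higher in BEGM. The test therefore cannot decide on this cause. A difference of this culture stays open and was not tested, as does a smaller share of EpiX material as a part of it. A lower share of mesenchymal cells, alone or as a part, also stays open.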

How the results depend on the processing

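The alternatives were planned, except the test with unnamed probe sets included and the list member counts without BEGM array 1 or the arrays of number 3, which were added after the data were seen. With the replicate block (the paired fit) 1252 genes were called, 778 of them shared with the 869 of the unpaired fit, and 15 lists. The block changed the calls of the named genes and 1 list given with a blocked p and moved the member counts given with the block by over 1.5 times, and changed no other such call and no other count by as much. The count of genes was 1212 with a random block, 876 after quantile normalization, 969 with median centring, 894 without the dimmest 25%, 885 with a trended and robust variance, 869 with the mean of probe sets and 1096 with unnamed probe sets. It moved to 1987 with array weights, which set the weight of BEGM array 1 at 0.527 and of EpiX array 2 at 3.57. It was 160 at an adjusted p under 0.01 and 1641 under 0.10, and 0 to 2089 with arrays left out. Of lists, 14 were called at the preset correlation, 0 with an estimated correlation and 8 by fry, and 12 to 15 with arrays left out. Over 1223 values of the 72 called named genes under these settings, 285 no longer passed and 0 reversed, and of 355 values of the 21 uncalled ones, 38 passed and 8 reversed. Besides those lost with the block or with arrays left out, the calls lost were those of Cd74 (adjusted p = 0.0529) and Hbegf (0.0573) with median centring, Hpgd (0.0577) and Cyp1b1 (0.0509) with a trended and robust variance, and Id4 (0.0515) with array weights. Called lists gave 280 values, of which 28 no longer passed and 0 reversed, and uncalled lists 258, of which 16 passed and 7 reversed. The reversals were all of uncalled results: Foxj1 (0.0509) and Cdkn1a (0.0159) with median centring, and camera's direction for the ciliated list (mean 0.0077) with array weights. With arrays left out, Scgb1a1 ran from -2.16 to 0.30 and Foxj1 from -0.27 to 0.18, and camera's direction turned at least once for the ciliated (mean 0.0153 to 0.0947), Wnt (-0.37 to -0.0806) and NRF2 and aryl hydrocarbon (-1.36 to -0.39) lists. The causes were not tested, but leaving out arrays also leaves fewer samples for the test.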

Other observations

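The gene families in this part were put together after the results were seen; the clock test was planned before its result was seen.

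Genes of 8 families were counted, each gene called by limma with BH adjustment over all genes. Some members are also in the fixed lists, so the counts are not separate from those lists. Inhba, Ltbp2 and Col4a1 are in the TGF-beta list, Tgfb2 in the YAP and TAZ list and Aqp3 in the basal list. Col1a1, Col1a2, Col3a1, Col5a1 and Col6a2 are in the fibroblast list, and Col2a1 and Col9a1 in the smooth muscle and cartilage list. The families were built around genes already known to differ, so no test of a family as a whole is given. Of 21 genes of the contractile apparatus 12 fell and 0 rose, with the myosin light chain Myl9 at -6.09 and the caldesmon Cald1 at -2.31. This family shares Cnn1 and Actg2 with the smooth muscle and cartilage list and Acta2 and Tagln with the TGF-beta list, and the fibroblast list also fell at the preset correlation (adjusted p = 0.405 with an estimated correlation), so these falls are not separate from those. Of 15 enzymes and chaperones of collagen hydroxylation and cross-linking 7 fell and 1 rose. These included the prolyl hydroxylase subunit P4ha3 (-6.74), the chaperone Fkbp10 (-5.05) and the lysyl hydroxylase Plod2 (-4.79), while P3h2 rose by 1.11. Of 20 collagen chains 0 were called, and 4 fell with the number as a block. Of 11 TGF-beta ligands, binding proteins and activating enzymes 7 fell, among them Inhba (-5.17), Bmp1 (-3.24), Ltbp3 (-2.68) and Tgfb3 (-1.43).

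In the remaining families 0 members fell. Of 17 kallikreins 4 rose, with Klk9 at 2.95 and Klk12 at 2.76 besides Klk10 and Klk13. Of 11 aquaporins 2 rose, Aqp5 and Aqp3, and the other 9 differed by -0.02 to 0.27. Of 11 carboxylesterases 4 rose, all of the Ces2 group, led by Ces2g at 3.14. Of 23 glutathione S-transferases 5 rose, led by Gsta4 at 2.24. Copies in the last 2 families are close in sequence, and signal shared between their probe sets was not tested.

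The secretoglobin Scgb3a1, a member of the secretory cell list, differed more between the media than nearly any gene that rose (5.72 ± 1.43, SE) without passing (adjusted p = 0.0675, and 0.0201 with the number as a block). It was at 5.26, 10.27 and 8.01 on the BEGM arrays 1, 2 and 3 and at 11.63, 13.33 and 15.75 on the EpiX arrays, higher in EpiX in 3 of 3 pairs. It was chosen after its values were seen.

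Among genes of the circadian clock, Nr1d1 (1.84 ± 0.31, SE), Nr1d2 (1.75 ± 0.38), Ciart (2.57 ± 0.48), Usp2 (3.44 ± 0.71), Tef (1.04 ± 0.21, adjusted p = 0.058 with the number as a block) and Per2 (1.18 ± 0.20) rose in EpiX, while Dbp (2.78 ± 0.74, adjusted p = 0.0804, and 0.0133 with the block) and Per3 (1.45 ± 0.36, adjusted p = 0.0661) did not pass. The clock genes Bhlhe40 (-3.18 ± 0.80, adjusted p = 0.0699, and 0.0392 with the block, lower in 3 of 3 pairs), Cry1 (0.19 ± 0.15, adjusted p = 0.528) and Cry2 (0.89 ± 0.32, adjusted p = 0.16) did not pass either, and Bhlhe40 lay in the other direction. A difference in circadian phase at harvest would lower the antiphase genes Bmal1, Npas2, Clock and Nfil3 while the outputs are high. The 4 antiphase genes had a median of 0.15 (SD 0.89), against 1.31 for the 4 measured outputs (Dbp, Tef, Per2 and Per3), a difference in the direction of a shift (exact permutation over 70 splits of the 8 genes, one-sided p = 0.0286). This p compares genes measured on the same arrays and does not measure the spread between cultures. The high outputs were the pattern that led to the test, and outputs that rose alone would also lower this p. The antiphase median was not under 0, as a shift would need. By the rule set before the result, a median of 0 or more spoke against a shift. It lay within the spread of its members, with Npas2 at -1.42 and Clock at 0.60, a bar that was not part of that rule. By this added bar a shift may or may not be present, and it cannot be told apart from a direct effect of the medium on these genes.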
